A study of Mus musculus with 4 samples.

How the data were processed

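The series profiled spleen cells of wild-type C57BL6 mice in steady state by CITE-seq, which counts messenger RNA and antibody-bound barcodes in the same single cells. Per the labels, dendritic cells (DCs) of 2 mice were enriched by negative selection, stained with 160 barcoded antibodies and 9 isotype controls (antibodies with no target in the cells), and sorted. The sort mixed 50000 to 60000 type 1 conventional DCs (cDC1), 10000 type 2 conventional DCs (cDC2) and 10000 random live cells. The gates were CD64-negative, CD11c-positive, MHCII-positive, and XCR1-positive CD172a-negative for cDC1 or the reverse for cDC2. Libraries were made with the 10x Genomics 3′ NextGEM chemistry. The labels give replicate numbers 1 and 2, each with an RNA and an antibody library. They do not state whether each replicate came from a mouse of its own, so p-values measure only the spread between these 2 libraries, which may be technical.

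The deposited matrix holds raw UMI counts per gene or antibody and cell, as whole numbers without normalization. It was written by Cell Ranger 3.1.0, per the file headers, with both libraries aggregated in a single matrix. STAR, Cell Ranger, Seurat 3.1.4 and the mm10 build are named in the submitters' processing notes. Whether depth was equalised at aggregation is not given in the sources used here. Barcode suffixes 1 and 2 told the libraries apart, and the numbering of libraries below follows the suffix. The matrix held 55385 genes and 190 antibody features, of which 172 had at least 100 UMIs and were used. A symbol shared by several gene identifiers was written with its identifier.

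Cells were kept with at least 500 genes, at least 1000 RNA UMIs and under 10% mitochondrial UMIs. Scrublet, as run in scanpy 1.11.5, then marked 546 doublets (4.30%) in library 1 and 1064 (6.24%) in library 2, which were removed. Library 1 had 13822 barcodes, 99617992 RNA UMIs and 13667427 antibody UMIs, and 12166 cells were kept. Library 2 had 17968 barcodes, 129565040 RNA UMIs and 17153368 antibody UMIs, and 15976 cells were kept. Intervals of shares are exact binomial 95% intervals and cover counting error only.

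Cells were clustered with counts scaled to 10000 per cell, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, with no integration. All 23 test lists of genes were left out of the clustering genes, which left 1881 genes. Clusters were named "-like" from marker genes fixed before the data were examined, with genes compared as CPM plus 10. A cluster was called mature-like when at least 50% of the 14 mature DC markers were 2-fold above the median of the other clusters. The lineage of a mature-like cluster came from surface XCR1 against CD172a, at least 2-fold apart.

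This lineage rule was the second version, chosen after the outcome of the first was seen. The first version, closer to the wording fixed beforehand, also required the RNA markers to point to the same lineage, and left unnamed the 776 cells of the cluster highest in mature DC markers (Ccr7 at 4836 CPM). In that cluster surface XCR1 was 2.64 and CD172a 0.722 UMIs per cell, against 0.805 and 7.39 in the mature-like cDC2 cluster. None of its 8 cDC1 marker genes was 2-fold above the other clusters, so its cDC1 name rests on surface proteins. Under the first version 3031 genes and 13 antibodies passed the test of mature-like against immature-like cDC1, in place of 5404 and 31.

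Mature-like and immature-like cDC1 were each clustered again (1500 variable genes without the test lists and the markers of cells other than cDC1 and mature DCs, 20 components, resolution 0.4). The mature-like subclusters highest and lowest in the mature DC markers are called late and early, which names an order in marker level and not in time. For a second definition of maturity, cells already named cDC1 were clustered on 163 antibodies alone (centred log ratio, 15 components, resolution 0.5). RNA clusters had set which cells these were, so only their split by maturity was free of RNA. A cluster was called mature-like when at least 50% of 8 surface maturation markers were 2-fold above the rest.

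Counts were summed per class and library and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr for RNA, library as a block because every class comes from the same cells of a library, two-sided, Benjamini-Hochberg at 0.05) in R 4.3.3. All named classes with at least 50 cells in each library shared the fit, or subclusters with at least 30. Genes that entered the clustering or served as naming markers were left out of the tests of classes and subclusters. The protein-defined comparison tested all genes that passed the filter, with antibody clusters as units and a contrast weighted by their cells. The design fixed beforehand also spoke of cells summed per class, and that version was added as an alternative. Standard errors (SE) were computed as the log2 fold change divided by the square root of F. CPM are per total RNA UMIs and antibody levels are per 10000 antibody UMIs, each as mean ± SD of 2 libraries. For immature-like subclusters the level of the others is a geometric mean over subclusters.

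Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) against all genes that passed the filter, with Benjamini-Hochberg adjustment over the 23 lists. Camera with an estimated correlation and fry were alternatives. Named genes are the 2 members of each list with the largest absolute log2 fold change among those past the threshold and changed the same way in both libraries, plus Abca1, Abcg1, Srebf1, Sqle, Itgb8, Cd274, Cd40, Ccl5, Ccl22, Cxcl9, Il12b and Mki67. In the protein-defined comparison they are the 10 highest and 10 lowest at 50 CPM or more in a class, for antibodies the 10 highest and 10 lowest, and for subclusters and the comparison with cDC2 the 5 highest and 5 lowest. Here too only those past the threshold and changed the same way in both libraries were eligible. Given beside these, and chosen after their values were seen, are Nr1h2, Nr1h3, Apoe, Arl4c, Arg2, Ifit3, Rsad2, Ciita and Abcg1 where the rule does not name them. So are the antibodies CD86, CD197, CD80, XCR1, CD8a and IgG1_Rat_l, and the genes given for clusters without a name. A few further genes and an antibody that the rule names are not reported here.

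The procedure was tested on simulated counts with known changes. Changed features were drawn from those above the median level, as many up as down, with classes taken as given. For mature-like against immature-like cDC1 they were 200 of 11888 genes. The rates therefore do not cover genes at low level, changes in as many genes as were called here, or the clustering step. For mature-like against immature-like cDC1 it recovered 93% of 100 genes changed by 1 log2 unit and 100% of 100 changed by 2, with 1 false call among 194. For antibodies it recovered 30% of 10 changed by 1 log2 unit and 100% of 10 changed by 2. Late against early recovery was 86% and 99%, and that of the protein-defined comparison was 85% and 100%, with 8 false calls among 193.

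Alternatives covered RLE size factors, DESeq2 1.42.0, no filter on low counts, no library block, DC classes only, doublets kept, a stricter cell filter (1000 genes, 5% mitochondrial UMIs), clustering resolutions, lists left in the clustering, other antibody scalings, and each library left out. Chosen after seeing the data was a reference for immature-like subclusters made of those with at least 5% of the class. Left out of every comparison were 4 clusters without a name (5.96% and 5.81% of cells) and neutrophil-like cells, too few per library.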

Results

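CITE-seq was done on wild-type mouse spleen in steady state to follow type 1 conventional dendritic cells (cDC1), which present antigens of dying cells to CD8 T cells, through maturation without infection. The 2 libraries gave 31790 barcodes, of which 28142 cells were kept, 12166 in library 1 and 15976 in library 2. The median cell had 6941.5 RNA UMIs, 2086 genes and 896 antibody UMIs in library 1, and 6884.5, 2089.5 and 823 in library 2. Both libraries belong to a single group, so every comparison is between cell classes found within them.

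Immature-like cDC1 were the most abundant class, with 7228 cells in library 1 (59.4%) and 10194 in library 2 (63.8%). Mature-like cDC1 numbered 789 (6.49%) and 1151 (7.20%), immature-like cDC2 1589 (13.1%) and 1687 (10.6%), and mature-like cDC2 174 (1.43%) and 241 (1.51%). The remaining named classes were T cell-like (890 and 766 cells), NK cell-like (396 and 612), B cell-like (130 and 158), erythroid-like (129 and 120), plasmacytoid DC-like (76 and 78) and neutrophil-like cells (40 and 41). These shares were set by the sort. Among cDC1, mature-like cells made up 9.84% (95% interval 9.20 to 10.5) in library 1 and 10.1% (9.60 to 10.7) in library 2. With other clustering resolutions this share was 4.24% and 5.78% or 15.7% and 15.4%, and with the test lists left in the clustering 5.31% and 3.62%. The number of mature-like cells in each lineage also moved, with 427 and 412 mature-like cDC1 and 739 (6.07%) and 848 (5.31%) mature-like cDC2 in that last setting. Immature-like cDC1 were then 62.6% and 68.7% of cells, and clusters without a name 2.08% and 2.55%. These counts therefore do not show cells passing from a lineage to the other. No mature-like cDC2 class was found at resolution 0.5. There the cluster highest in mature markers (1180 cells, Ccr7 at 4762 CPM) had no name, and the mature-like cDC1 class was a single cluster with Ccr7 at 508.9 CPM. At resolution 1.5 mature-like cDC1 numbered 809 and 1214, and clusters without a name held 24.7% and 22.4% of cells. With the first lineage rule, from RNA and surface together, the share was 5.16% and 7.03%. That rule was closer to the wording fixed beforehand than the main one, which was chosen after seeing the data.

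The first question was which RNAs separate mature from immature cDC1 in the steady-state spleen. Il12b, a subunit of interleukin 12, reached 1024 ± 284 CPM (SD, n = 2) against 22.3 ± 2.84 in immature-like cells, a log2 fold change of 5.65 (SE 0.18, adjusted p = 4.9e-24). Ccl5, a T cell-attracting chemokine, reached 2989 ± 1583 against 37.0 ± 3.62 CPM (SD, n = 2; log2 6.47, SE 0.23, adjusted p = 1.5e-22). Cell cycle genes moved the other way, with Mki67, a proliferation marker, at 8.73 ± 0.471 against 20.1 ± 0.777 CPM (SD, n = 2; log2 -1.08, SE 0.18, adjusted p = 6.0e-06). In camera with an estimated correlation the cell cycle list was not past the threshold (adjusted p = 0.0936). At clustering resolution 1.5 Mki67 was higher, not lower, in mature-like cells, as given below. Of 11086 genes tested, 2426 rose and 2978 fell, 5404 in all. The count was 2808 at clustering resolution 0.5, without the Ccr7-high cluster. It was 3031 with the first lineage rule, from RNA and surface together, which was closer to the wording fixed beforehand. Of 42 named genes higher in the class, 39 were highest in subcluster 2 of the mature-like cells, the highest in maturation markers, and 14 were below immature-like cells in at least 1 subcluster. The naming marker Ccr7 differed between libraries within the class, at 2291 CPM in library 1 and 1318 in library 2. The class was also a different mix in each library. Subcluster 0 (Ccr7 at 39.6 CPM) held 155 and 452 cells in libraries 1 and 2, and subcluster 2 (Ccr7 at 4621 CPM) held 411 and 410.

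All 18 tested NF-kB pathway genes rose (adjusted p = 9.8e-15 for the list, 0.0373 with an estimated correlation). Relb, a subunit of the noncanonical pathway, changed by log2 3.83 (SE 0.13) and Traf1, an adaptor of TNF receptors, by 3.46 (SE 0.13). Of 11 costimulation genes 10 rose and 1 fell (adjusted p = 2.2e-07, 0.0190 with an estimated correlation), with Cd70 at log2 7.24 (SE 0.31), Slamf1 at 4.79 (SE 0.44) and Cd40 at 3.68 (SE 0.12). Of 18 coinhibition and tolerance genes 13 rose and 2 fell (adjusted p = 1.3e-05, 0.0373 with an estimated correlation). Among them Arg2, an arginase, changed by log2 7.05 (SE 0.39), Il27, a cytokine subunit, by 6.21 (SE 0.35), and Cd274, which encodes PD-L1, by 4.31 (SE 0.16). Of 20 cytokine and chemokine genes 14 rose and 3 fell (adjusted p = 1.3e-06, 0.0373 with an estimated correlation). Ccl22, a ligand of CCR4, stood at 204.1 ± 38.0 against 3.55 ± 1.31 CPM (SD, n = 2) and Cxcl9, a ligand of CXCR3, at 2214 ± 185 against 313.5 ± 54.2. The Cxcl9 level came from part of the class, at 4449 CPM in the mature-like subcluster lowest in maturation markers and 126.4 in the highest, which is below immature-like cells. T, B and NK cell-like cells had 169.8 CPM on average, and background RNA was not measured.

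Of 26 type I interferon-stimulated genes 23 rose and 0 fell (median log2 2.01, adjusted p = 2.6e-12, 0.0373 with an estimated correlation), among them Rsad2 (log2 4.53, SE 0.18) and Ifit3 (log2 4.28, SE 0.37), both antiviral. Ifit3 was at 11.8 CPM in the mature-like subcluster lowest in maturation markers and at 0.582 and 0 in the others, against 0.264 in immature-like cells. With the stricter cell filter it stood at log2 -0.59. The list was not past the threshold with maturity defined from surface proteins (adjusted p = 0.212). That definition set mostly late cells against all other cDC1, as given below, so it does not test the same contrast. All 13 interferon gamma-inducible GTPases and regulators rose (median log2 3.13, adjusted p = 2.8e-12, 0.0190 with an estimated correlation), with Gbp5 at log2 5.80 (SE 0.18) and Gbp4 at 5.41 (SE 0.15). Of 16 DC transcription factors 9 rose and 0 fell (adjusted p = 3.9e-05, 0.149 with an estimated correlation), including Stat4 at log2 3.45 (SE 0.22) and Irf4 at 2.62 (SE 0.23). Of 19 MHC class I pathway genes 12 rose and 1 fell (adjusted p = 5.0e-05, 0.149 with an estimated correlation), including their transactivator Nlrc5 at log2 2.35 (SE 0.15). Of 25 lysosome genes 13 rose and 3 fell (adjusted p = 0.0213, 0.130 with an estimated correlation), with the tetraspanin Cd63 at 410.8 ± 149 against 2.11 ± 0.158 CPM (SD, n = 2).

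The series title names LXR, a nuclear receptor activated by cholesterol derivatives, and 3 lists dealt with cholesterol. Of 15 cholesterol efflux and LXR target genes 6 rose and 2 fell, and the list was not past the threshold (adjusted p = 0.181). The exporter Abcg1 rose from 31.5 ± 0.108 to 122.5 ± 39.7 CPM (SD, n = 2; log2 2.08, SE 0.13), and Arl4c changed by log2 1.94 (SE 0.14). The related exporter Abca1 had 0 UMIs in mature-like cDC1, where 3 counts would be 0.208 CPM, and 0.0774 CPM in immature-like cells, so no fold is given. Srebf1, a regulator of fatty acid synthesis, had a log2 change of -0.31 (adjusted p = 0.120). Of the receptors themselves, Nr1h2 changed by log2 0.37 (adjusted p = 0.00469) and Nr1h3 had 1.17 (adjusted p = 0.123) at 0.775 CPM in mature-like cells. Of 23 cholesterol biosynthesis and uptake genes 13 rose and 2 fell (median log2 0.48, adjusted p = 0.0186, 0.307 with an estimated correlation). The isomerase Idi1 changed by log2 1.52 (SE 0.15) and Sqle by 0.92 (SE 0.15). Of 9 cholesterol trafficking and storage genes 3 rose and 5 fell (adjusted p = 0.978), including Gramd1b at log2 1.24 (SE 0.18) and Tmem97 at -1.31 (SE 0.23). Gramd1b was at 24.8 CPM in mature-like subcluster 2 and at 4.03 and 3.09 in subclusters 0 and 1, against 4.87 in immature-like cells. It stood at log2 -0.21 at clustering resolution 0.5 and at -0.43 with lineage from RNA and surface together.

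All 40 cell cycle genes fell (median log2 -2.43, adjusted p = 9.0e-22, 0.0936 with an estimated correlation), including the mitotic genes Plk1 at -4.61 (SE 0.41) and Nusap1 at -4.32 (SE 0.26). At clustering resolution 1.5 Mki67 stood at log2 1.21. Of 76 oxidative phosphorylation genes 55 fell and 0 rose (adjusted p = 1.5e-07, 0.307 with an estimated correlation). The other lists were not past the threshold. They were homing receptors (2 rose and 8 fell of 14, adjusted p = 0.0810), MHC class II pathway (6 and 5 of 15, 0.344), pattern recognition (4 and 7 of 21, 0.691) and apoptotic cell uptake (3 and 0 of 10, 0.0823). Also not past it were the actin cytoskeleton (6 and 3 of 22, 0.203), glycolysis and hypoxia (2 and 9 of 18, 0.103), immediate early and heat shock genes (8 and 4 of 26, 0.318), apoptosis regulators (6 and 3 of 12, 0.0823) and ribosomal proteins (0 and 5 of 76, 0.134). Single members still changed, such as the monocyte chemokine receptor Ccr2 at log2 -1.93 (SE 0.16), H2-Eb2 at 4.10 (SE 0.15), the beta-glucan receptor Clec7a at 2.66 (SE 0.14) and proapoptotic Bcl2l11 at 3.20 (SE 0.15). Mfge8, which bridges dying cells to phagocytes, changed by log2 2.44 (SE 0.21), from 32.3 CPM in mature-like subcluster 2 alone (0.924 and 1.51 in subclusters 0 and 1, 2.32 in immature-like cells), but stood at -1.01 at clustering resolution 0.5 and -0.91 with lineage from RNA and surface together. Counts adjusted over the list alone were the same except in cytokines (15 rose), MHC class I (13 rose), lysosome (14 rose), oxidative phosphorylation (1 rose, 58 fell) and ribosomal proteins (1 fell).

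Marker genes of other cells were measured beside these changes. Red pulp macrophage markers were higher in mature-like cDC1 (median log2 3.08 over 4 tested, adjusted p = 0.0107), with Vcam1 at 67.9 against 4.70, Hmox1 at 91.1 against 22.01 and Spic at 40.2 against 0.955 CPM. The abundant macrophage genes C1qa (0.831 against 1.19 CPM) and C1qb (0.810 against 1.29) were not higher. cDC2 markers had a median of log2 1.57 (adjusted p = 0.0549), with S100a4 at 23.4 against 9.63 CPM, and cDC1 markers -0.37 (adjusted p = 0.0556). B cell (log2 1.81, adjusted p = 0.190), T cell (0.97, 0.211), erythroid (0.92, 0.190), NK cell (0.75, 0.692), plasmacytoid DC (0.24, 0.692), neutrophil (0.14, 0.692), plasma cell (-0.55, 0.352) and nonclassical monocyte markers (-0.41, 0.426) were not past the threshold. Itgb8, an integrin subunit named beforehand, was too low to test, at 0.733 CPM in mature-like and 0.00757 in immature-like cDC1.

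**Figure D1:**
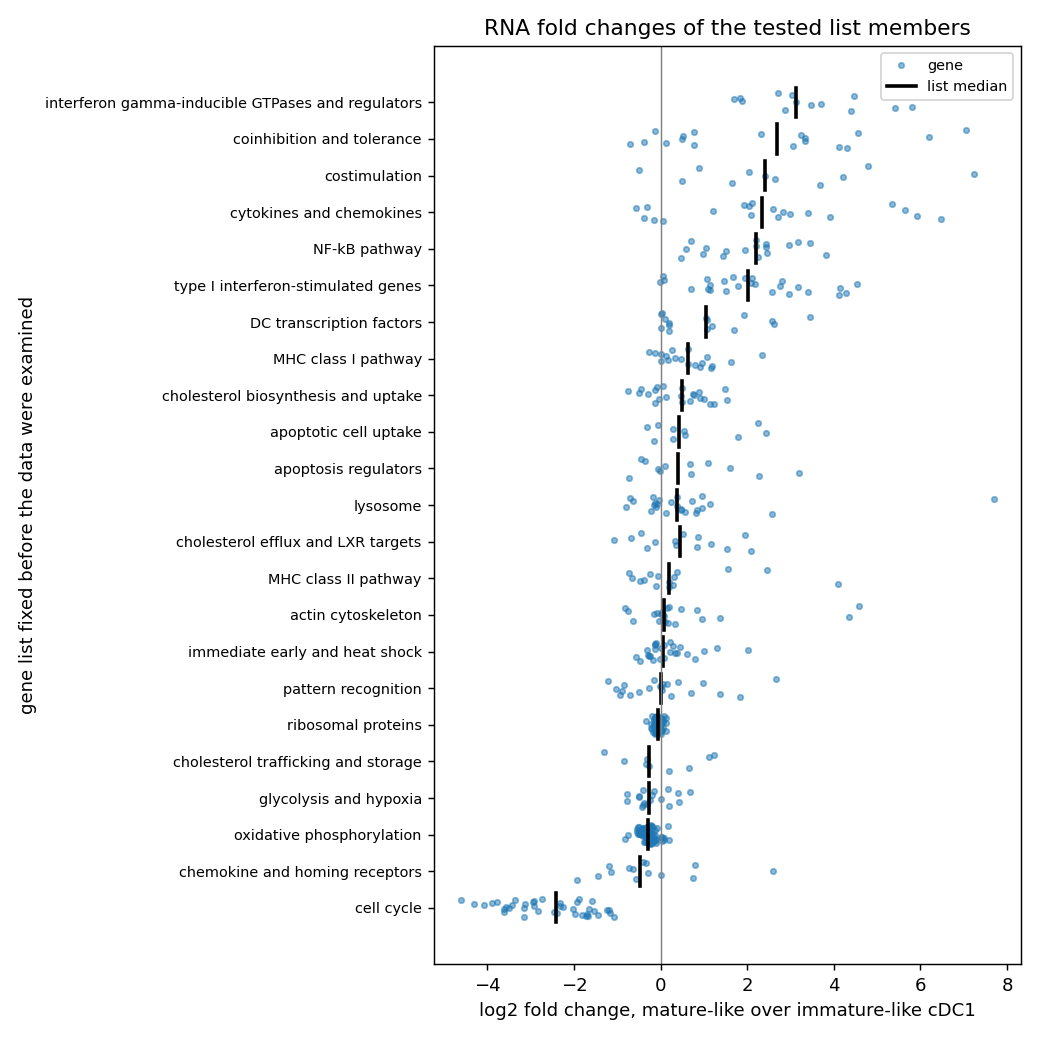
Log2 fold changes of mature-like over immature-like cDC1 for the tested members of 23 gene lists, a dot per gene and a black line at each list's median, without Abca1, which had 0 UMIs in mature-like cells. The interferon gamma-inducible list had its median at 3.13 and the cell cycle list at -2.43.

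Surface antibodies on the same cells were compared next. The lysosomal tetraspanin CD63 rose on the surface from 4.13 ± 0.128 to 67.6 ± 32.0 per 10000 antibody UMIs (SD, n = 2; log2 4.14, SE 0.31, adjusted p = 1.1e-06). CD83, a maturation marker, rose from 2.12 ± 0.162 to 9.11 ± 1.37 (SD, n = 2; log2 2.24, adjusted p = 0.000275), and CD274 (PD-L1) from 17.4 ± 3.95 to 47.8 ± 5.96 (SD, n = 2; log2 1.59, adjusted p = 0.000775). Of 172 antibodies 15 rose and 16 fell, 31 in all. Also higher were the feature named CD278_0171 (log2 1.91), P2RY12 (1.45), the lysosomal protein CD107a (1.38), CD127 (1.35), MHC class II (IA_IE, 1.30), which was a gate of the sort, ESAM (1.29) and Ly6G_Ly6C (1.29). The costimulatory CD86 changed by log2 1.16 (adjusted p = 0.000365) and CD197, the receptor CCR7, by 1.16 (adjusted p = 0.00416).

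The antibodies that fell included CD300LG (log2 -1.51), CD226 (-1.10), CD43 (-1.08), CD22 (-1.04), CD115 (-0.91), CD102 (-0.91), CD49f (-0.69), CD9 (-0.69) and CD272 (-0.62). CD300LG (0.403 against 1.27 per 10000), CD127 (1.05 against 0.452) and Ly6G_Ly6C (at most 0.638) lay below 1.805, the highest isotype level without IgG1_Rat_l. CD8a (log2 -0.34, adjusted p = 0.345) and CD80 (-0.08, 0.939) were not past the threshold. Among the 31 was the isotype control IgG1_Rat_l (log2 3.94, adjusted p = 0.0256), with 5.44 in library 1 and -1.09 in library 2. Over all cells, single cells held 77.6% of its UMIs in library 1 and 45.7% in library 2. Within the classes compared, a single mature-like cell held 97.6% of the UMIs of its class in library 1. In library 2 a single immature-like cell held 56.6%. The rise of this control in library 1 thus came from a single cell. With isotype UMIs as library size 0 antibodies passed (edgeR, 2 at an unadjusted p under 0.05), and without IgG1_Rat_l 13 did, of which 12 rose and 1 fell, so the number of antibodies that fell depended on the scaling. The count was 12 and 17 at clustering resolutions 0.5 and 1.5, and 13 with lineage from RNA and surface together. Among the 31 antibodies above the highest isotype level, which IgG1_Rat_l set, 12 passed, and without IgG1_Rat_l, which was left out of the 92 then above the level, 33 of 91 passed, the settings without IgG1_Rat_l being chosen after seeing the data.

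**Figure D2:**
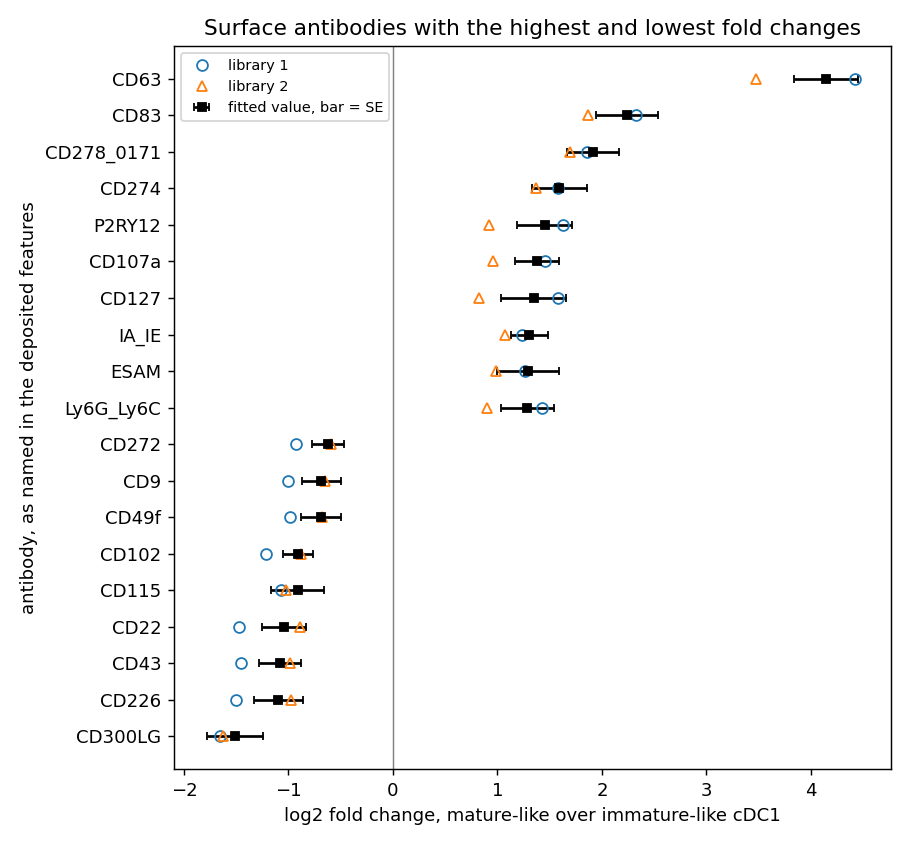
Log2 fold changes of mature-like over immature-like cDC1 for 19 antibodies, with the fitted value and its SE as a square with a bar and the per-library values, from plain totals, as a circle (library 1) and a triangle (library 2). CD63 stood at 4.14 and CD300LG at -1.51. Both libraries lay on the same side of 0 for each antibody because the rule for naming required it. IgG1_Rat_l, whose libraries went opposite ways, was left out by that rule. CD300LG, CD127 and Ly6G_Ly6C lay below the highest isotype level without IgG1_Rat_l.

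Mature-like cDC1 were divided into subclusters. Subcluster 0 (607 cells, 155 and 452 per library), called early, had Ccr7 at 39.6 CPM and Xcr1 at 588, subcluster 1 (481 cells, 206 and 275) had Ccr7 at 775, and subcluster 2 (821 cells, 411 and 410), called late, had Ccr7 at 4621, Fscn1 at 1705 and Xcr1 at 98.3 CPM. Early cells were led by interferon-induced genes such as Slfn5, Ly6a, Irf7 and Iigp1, and their mature marker score of 5.06 was close to the 4.87 of an immature-like subcluster. From early to late, Cxcl9 went from 4449 ± 1151 to 126.4 ± 9.23 CPM (SD, n = 2; log2 -4.96, SE 0.15, adjusted p = 1.4e-34) and Ccl5 from 49.5 ± 9.93 to 8176 ± 1834 (SD, n = 2; log2 7.45, SE 0.12, adjusted p = 2.3e-47). The late levels of Cxcl9 and Xcr1 were near those of other lineages. T, B and NK cell-like cells had Cxcl9 at 169.8 CPM on average, and T cell-like cells had Xcr1 at 57.1 and 94.4 CPM in libraries 1 and 2. Of 9578 genes tested, 2298 were higher and 3037 lower in late than in early cells. The median over all genes was log2 -0.16 with TMM, 0.00 with RLE and -0.34 with totals alone, and 51.7% of calls were higher with RLE against 43.1% with TMM.

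Interferon-stimulated genes were lower in late than in early cells, with 20 of 25 lower and 3 higher (median log2 -1.84, adjusted p = 1.6e-05, 0.188 with an estimated correlation). Irf7, an interferon-induced transcription factor, went from 337.5 ± 39.3 to 20.01 ± 2.34 CPM (SD, n = 2; log2 -3.85) and Ifit3 was 0 in late cells, at least 4.16 log2 units lower (bound -4.16, from 3 counts over the subcluster). Rsad2 stood apart, at 33.2 CPM in subcluster 0, 6.25 in subcluster 1 and 37.6 in subcluster 2. Interferon gamma-inducible genes went both ways (5 higher, 6 lower of 13, adjusted p = 0.798), with the GTPases Iigp1 at log2 -5.75 and Irgm1 at -4.23. All 18 NF-kB genes were higher in late cells (adjusted p = 4.0e-12, 0.188 with an estimated correlation), as were 8 of 10 costimulation genes, with 2 lower (0.00165, 0.215). Arg2 was 0 in early cells and 30.5 CPM in late, at least 5.87 log2 units higher.

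Of 24 cholesterol biosynthesis and uptake genes 18 were higher in late cells and 1 lower (median log2 0.98, adjusted p = 0.000489, 0.221 with an estimated correlation). Of 12 LXR target genes 6 were higher and 1 lower (adjusted p = 0.0446, 0.221 with an estimated correlation, and 0.0502 with RLE, which ended the call). Abcg1 rose from 35.4 ± 2.58 to 279.1 ± 30.05 CPM (SD, n = 2; log2 3.10, SE 0.11), Arl4c by log2 3.30 and Apoe, a cholesterol carrier, by log2 1.74. Trafficking and storage genes went both ways (3 and 3 of 9, adjusted p = 0.798).

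Further lists passed with the preset correlation and not with an estimated correlation. MHC class I genes were higher (12 higher, 4 lower of 19, adjusted p = 0.00142, 0.299 estimated), as were DC transcription factors (11 and 2 of 16, 0.00220, 0.270). Lower in late cells were MHC class II genes (4 higher, 11 lower of 15, 0.000968, 0.221), homing receptors (2 and 7 of 11, 0.0267, 0.188), pattern recognition (3 and 10 of 18, 0.0161, 0.188) and glycolysis (1 and 12 of 17, 0.00155, 0.188). So were oxidative phosphorylation (2 and 65 of 76, 5.4e-14, 0.221) and ribosomal proteins (1 and 64 of 76, 2.5e-12, 0.373). Ciita, the MHC class II transactivator, went from 275.2 to 46.4 CPM, while H2-Eb2 rose by log2 4.93. Not past the threshold were coinhibition (10 and 4 of 17, adjusted p = 0.122), cytokines (10 and 6 of 19, 0.296), apoptotic uptake (4 and 2 of 10, 0.407), lysosome (12 and 10 of 25, 0.645), actin (12 and 5 of 21, 0.0770), cell cycle (6 and 12 of 40, 0.239), immediate early genes (9 and 11 of 26, 0.319) and apoptosis regulators (6 and 3 of 12, 0.0575). Counts adjusted over the list alone differed in LXR targets (3 lower), DC transcription factors (3 lower), oxidative phosphorylation (66 lower) and immediate early genes (12 lower).

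**Figure D3:**
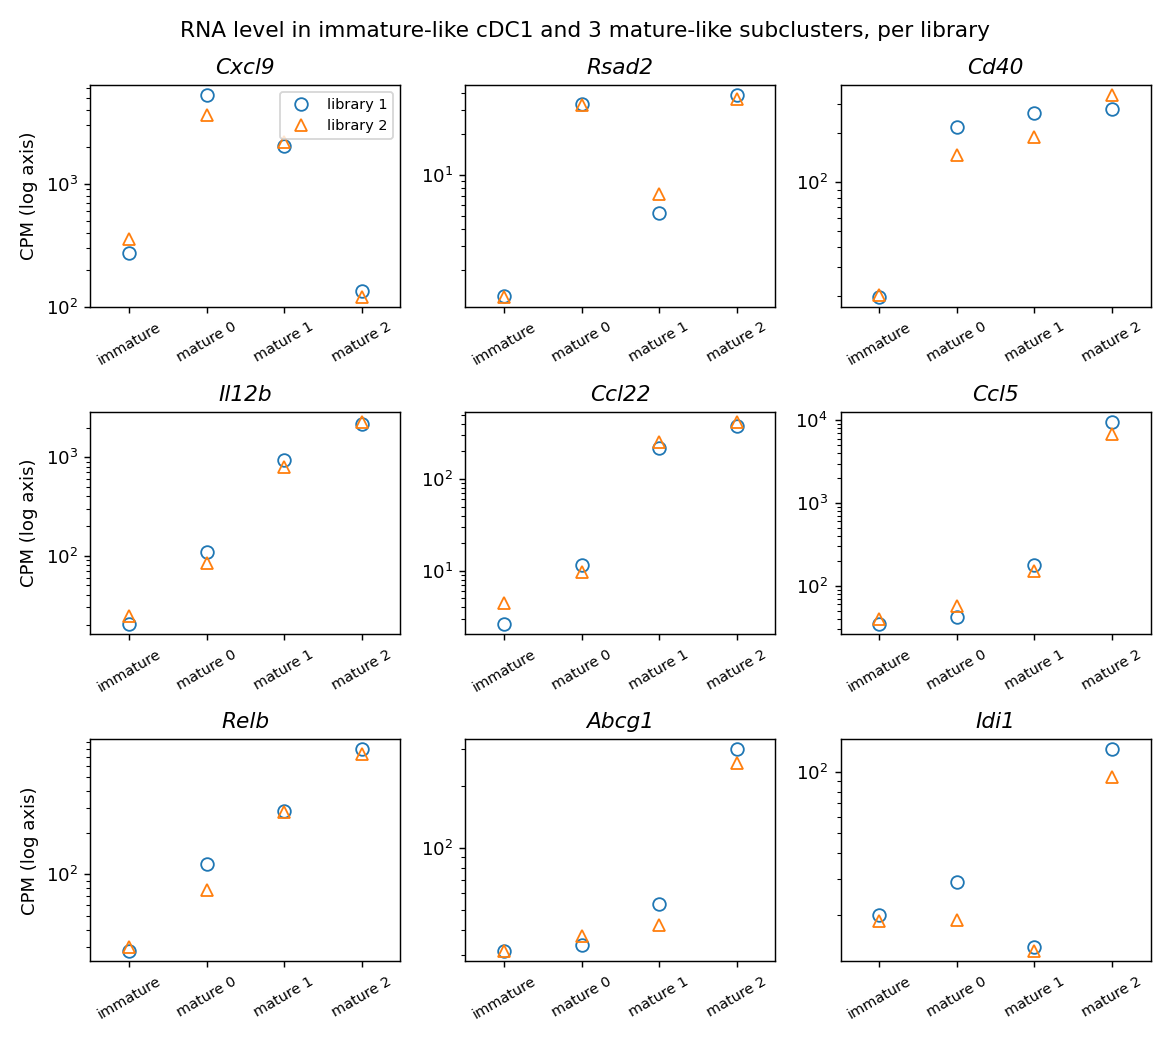
CPM (log axis) of 9 genes in immature-like cDC1 and mature-like subclusters 0, 1 and 2, a circle for library 1 and a triangle for library 2. Cxcl9 was at 4449 CPM in subcluster 0 and 126.4 in subcluster 2, while Ccl5 was at 49.5 and 8176.

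On the surface 73 of 172 antibodies differed between late and early cells, 36 higher and 37 lower. Among them was the isotype control IgG1_Rat_l (log2 5.48, adjusted p = 0.0300), with 6.29 in library 1 and -0.67 in library 2. CD63 rose from 5.12 ± 0.201 to 139.1 ± 35.6 per 10000 (SD, n = 2; log2 5.08, adjusted p = 1.2e-10), and P2RY12 (log2 2.60), CD197 (2.58), CD278_0171 (2.39) and CD127 (2.27) were also higher. The stem cell factor receptor CD117 went from 210.0 ± 21.0 to 47.0 ± 14.4 (SD, n = 2; log2 -1.86, adjusted p = 2.9e-09), with CD300LG (-1.18), CD366 (-1.15), CD102 (-1.15) and CD105 (-1.14) also lower. Of these CD127 and CD300LG lay below the isotype level of 1.805. XCR1, a gate of the sort, was lower in late cells (log2 -0.87, adjusted p = 1.0e-06), as was CD8a (-0.54, adjusted p = 0.000950).

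Immature-like cDC1 held 5 subclusters with at least 5% of the class, each compared with the mean of the others, weighted equally and including a sixth of 360 cells (2.07%). A reference of the large subclusters alone, without that sixth, was an alternative chosen after seeing the data. Subcluster 1 (2840 cells, 16.3%) was the proliferating group, with all 40 cell cycle genes higher (adjusted p = 1.3e-53, 0.0592 with an estimated correlation) and Cenpf at log2 7.16 (SE 0.11) and Mki67 at 6.17 (SE 0.11). Its lysosome genes were lower (1 higher and 15 lower of 25, adjusted p = 1.9e-05, 0.0293 with an estimated correlation, and 0.0982 with both an estimated correlation and the large reference), and 12 of 15 MHC class II genes were lower with 0 higher (2.2e-09, 0.178). On its surface CD22 (log2 0.94) and CD226 (0.86) were higher. Subcluster 4 (886 cells, 5.09%) had higher Gpr183 (log2 4.38, SE 0.18), Ccr2 (3.38, SE 0.08) and Vim (3.14, SE 0.05). On its surface CD300LG (log2 3.06), CD226 (2.43), CD43 (1.86) and CD11b (1.51) were higher and CD8a (-2.07), CD207 (-1.81), CD201 (-1.79), CD38 (-1.48) and CD103 (-1.44) lower. In these cells 21 of 24 cholesterol biosynthesis genes were higher and 0 lower (adjusted p = 7.6e-18, 0.00940 with an estimated correlation), as were 7 of 11 homing receptors with 1 lower (9.1e-07, 0.00940) and 14 of 25 interferon-stimulated genes with 0 lower (1.4e-07, 0.282).

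Subclusters 0 (3869 cells, 22.2%) and 3 (5585 cells, 32.1%) had higher immediate early and heat shock genes with either reference. In subcluster 0, 22 of 26 were higher and 3 lower (adjusted p = 1.9e-10, 0.243 with an estimated correlation), as were 16 of 18 NF-kB genes with 0 lower (4.1e-07, 0.243), and Tnf (log2 3.90), Nr4a3 (2.92) and Egr3 (2.77) were among the highest. In subcluster 3, 25 of 26 immediate early and heat shock genes were higher (adjusted p = 1.2e-29, 0.0587 with an estimated correlation), including Ier3 (log2 1.72) and Egr1 (1.41), and 32 of 40 cell cycle genes lower (3.9e-13, 0.148). Subcluster 2 (3882 cells, 22.3%) had higher Ccnb2 (log2 3.40), a mitotic cyclin, and Pdia4 (1.77), an endoplasmic reticulum chaperone, with 10 of 24 cholesterol biosynthesis genes higher (0.0150, 0.387 with an estimated correlation), a call that ended with the large reference (0.163). Its cell cycle list went both ways (12 higher and 21 lower of 40, adjusted p = 0.456). With the large reference 11 were higher and 25 lower (0.00269, with the preset correlation only). With the large reference the immediate early and heat shock list had 17 higher and 6 lower in subcluster 0 (3.3e-05) and 15 and 3 in subcluster 3 (2.4e-05), both with the preset correlation only. It turned from higher to lower in subclusters 2 (17 higher and 2 lower to 0 and 22) and 4 (17 and 4 to 3 and 15). Ribosomal protein genes were lower in subclusters 0 (76 of 76, 9.3e-34, 0.243 with an estimated correlation) and 1 (75, 7.3e-47, 0.180), and 60 and 59 were lower with the large reference. In subclusters 2, 3 and 4 the ribosomal call ended or reversed with that reference, as did the oxidative phosphorylation calls of subclusters 1, 3 and 4. Oxidative phosphorylation genes stayed lower in subcluster 0 (73 of 76, 1.9e-34, 0.233 with an estimated correlation, and 72 with the large reference). Subclusters 0 to 4 had 5785, 4910, 2561, 3108 and 1769 genes and 45, 27, 18, 22 and 55 antibodies past the threshold. With RLE, 45.8% of calls in subcluster 2 and 48.1% in subcluster 3 were higher, against 62.2% and 55.0% with TMM. Adjusted over the list alone, 14 MHC class II genes were lower in subcluster 1, 15 interferon-stimulated genes higher in subcluster 4, and 34 cell cycle genes lower in subcluster 3 and 22 in subcluster 2. In subcluster 4, 18 immediate early and heat shock genes were higher and 5 lower, and the other list counts given for the first reference were the same. With the large reference 48, 23, 11, 34 and 54 antibodies passed in subclusters 0 to 4. Without the library block 25, 16, 5 and 9 antibodies passed in subclusters 0 to 3.

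Within the cells named cDC1 from RNA clusters, a split by surface proteins alone found 676 mature-like cells (346 and 330 per library). Their cluster just met the rule, with 4 of 8 markers 2-fold higher. By RNA 94.97% of these cells were mature-like and 90.5% late. The other antibody clusters still held 2.26% to 10.3% of cells mature-like by RNA, and 0.0260% to 3.84% late. The split thus set mostly late cells against a rest that included mature-like cells that were not late. Fscn1, an actin bundler of mature DCs, stood at 1976 ± 206 against 8.85 ± 0.0763 CPM (SD, n = 2; log2 8.14, SE 0.10, adjusted p = 3.6e-29) and Tnfrsf4, encoding OX40, at 624.8 ± 37.8 against 2.89 ± 0.475 (SD, n = 2; log2 8.02). Also high were Insm1 (log2 8.62), Dscaml1 (8.57), Synpo2 (8.40), Tmem150c (8.24), Prph (8.17), Ankrd33b (8.08), Slco5a1 (7.86) and Ccl5 (7.74). Among genes at 50 CPM or more, the lowest were Serpinf1 (log2 -3.23), BC028528 (-2.98), P2ry6 (-2.93), Iqgap2 (-2.91), Ssbp4 (-2.85), the lysosomal gene Cd68 (-2.81), Ppfia4 (-2.73), Unc119b (-2.72), Egr3 (-2.72) and March1 (-2.70), a ligase that removes MHC class II from the surface. Of 13127 genes 3533 were higher and 3986 lower.

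In this comparison 13 of 19 MHC class I genes were higher and 4 lower (adjusted p = 1.8e-08, 0.0318 with an estimated correlation). All 18 NF-kB genes were higher (8.0e-22, 0.135 with an estimated correlation), as were 15 of 24 cholesterol biosynthesis genes with 1 lower (9.3e-05, 0.271) and 6 of 14 LXR targets with 4 lower (0.0426, 0.212). Interferon-stimulated genes went both ways (10 and 7 of 26, adjusted p = 0.212), while 8 of 13 interferon gamma-inducible genes were higher and 3 lower (2.8e-06, 0.193). Cell cycle genes were lower (37 of 40, 1 higher, 1.3e-09, 0.284), as were 70 of 78 oxidative phosphorylation genes with 2 higher (5.4e-16, 0.269). Adjusted over the list alone, 16 biosynthesis genes were higher and 2 lower, and the other counts named here were the same.

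Maturation was also compared between cDC1 and cDC2, the other conventional lineage. Apoe rose in cDC1 from 62.4 ± 0.973 to 169.6 ± 68.7 CPM and fell in cDC2 from 190.9 ± 13.3 to 26.9 ± 13.9 (SD, n = 2; difference log2 4.15, SE 0.29, adjusted p = 9.6e-13, with 5.28 in library 1 and 3.25 in library 2). Cd200, an inhibitory ligand, rose from 8.19 ± 1.33 to 62.9 ± 22.8 CPM in cDC1 and from 2.23 ± 0.0854 to 155.3 ± 20.5 in cDC2 (SD, n = 2; difference log2 -3.24, SE 0.32, adjusted p = 1.4e-09). The starting classes were unlike in the naming marker Ccr7, at 225.6 CPM in immature-like cDC2 and 9.90 in immature-like cDC1. In cDC2 maturation 1368 of 11086 genes rose and 1349 fell. The change differed between lineages for 1157 genes, with 693 higher and 464 lower in cDC1 than in cDC2. With late mature-like cDC1 alone, a setting chosen after seeing the data, 2301 genes differed.

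Maturing cDC2 had 16 of 18 NF-kB genes higher and 1 lower (adjusted p = 5.4e-11, 0.0882 with an estimated correlation), 16 of 20 cytokine genes higher and 2 lower (3.5e-10, 0.0509), 15 of 19 MHC class I genes higher and 0 lower (8.8e-10, 0.0882) and 31 of 40 cell cycle genes lower with 0 higher (7.4e-10, 0.239). Of 23 cholesterol biosynthesis genes 12 were higher and 0 lower (adjusted p = 5.1e-05, 0.161 with an estimated correlation), and of 15 LXR targets 4 were higher and 4 lower (0.848). Interferon-stimulated genes went both ways (5 and 8 of 26, adjusted p = 0.176). Adjusted over the list alone, 17 cytokine and 16 MHC class I genes were higher and 33 cell cycle and 9 interferon-stimulated genes lower, the other counts being the same. The difference of these lists between lineages was not tested.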

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

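The test with late mature-like cDC1 alone was chosen only after the differences between cDC1 and cDC2 were seen. A test of the difference itself singled out 1157 genes whose change on maturation was unlike in the 2 lineages. The change in cDC1 minus that in cDC2 was log2 4.15 for Apoe, 4.03 for Isg20, 3.94 for Bex6, 3.81 for Ndst1, 3.57 for Cd300lf, -3.24 for Cd200, -3.22 for Cdk6, -3.00 for Col27a1, -2.81 for Gnl2 and -2.70 for Serpinf1. Libraries 1 and 2 lay far apart for Apoe (5.28 and 3.25), Ndst1 (5.77 and 2.93) and Serpinf1 (-3.84 and -1.96). The immature-like classes were also unlike, with Ccr7 at 225.6 CPM and Fscn1 at 23.8 in cDC2, against 9.90 and 2.25 in cDC1. A cluster of 973 cells with high surface CD172a had no name and was left out of cDC2. What these differences add to the calls was not tested. Mature-like cDC2 were a single cluster with Ccr7 at 4461 CPM, not divided further, whereas mature-like cDC1 mixed early and late cells. If that mixture were the source, under 80% of the calls would recur with late cDC1 alone, and 56.75% did (555 of the 978 tested in both), while 22 were past the threshold in the opposite direction. The limit of 80% was also set after seeing the data. Calls near the threshold can be lost with the fewer cells of late cDC1 alone, so the share cannot single out the mixture. With late cDC1 alone 2301 genes differed, more than before. That count cannot decide on the mixture, since mature-like cDC2 stayed undivided and may differ in stage from late cDC1. A difference in the mix of early and late cells may account for part of the list, and a difference between the lineages stays open for the calls that recurred. Of the genes named above these were Apoe (log2 4.34 with late cells alone), Cd300lf (2.76), Isg20 (1.65), Gnl2 (-2.51), Cd200 (-1.75) and Serpinf1 (-4.61). Bex6 was no longer past the threshold (2.09, adjusted p = 0.283 in edgeR). Ndst1, Cdk6 and Col27a1 had no value in that setting.

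A cluster left without a name (304 cells, 93 and 211 per library) carried hemoglobin RNA beside cDC1 markers, with Hbb-bs at 7384 CPM and Xcr1 at 549 as means of 2 libraries, against 17.0 and 19.9 CPM of Hbb-bs in immature-like cDC1. The surface erythroid protein TER119 was at 0.0645 and 0.0427 UMIs per cell in it, and at 0 to 0.0599 in the other clusters without a name. Its level in erythroid-like cells was not measured here, so it cannot tell what these cells are.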

How the results depend on the processing

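Late mature-like cDC1 alone, the large reference of immature-like subclusters and the settings without IgG1_Rat_l were chosen after seeing the data. Lineage from RNA and surface together and cells summed into classes were closer to the design fixed beforehand, but became alternatives only later. The main lineage rule was itself chosen after seeing the data. The other alternatives were planned. Over all alternatives the count of genes that separated mature-like from immature-like cDC1 ran from 2808 (clustering resolution 0.5) to 6810 (test lists left in the clustering). It was 3031 when lineage came from RNA and surface together. Of the 5404 main calls, 2587 recurred at resolution 0.5, 2582 of them in the same direction, and 2783 with that lineage rule, 2775 in the same direction. Without the low-count filter 25.9% of calls were higher, against 44.9%. Of 31 antibodies past the threshold (48.4% higher), counts moved to 0 with isotype UMIs as library size and to 13 without IgG1_Rat_l (92.3% higher). Above the isotypes 12 passed (25% higher), or 33 of 91 when IgG1_Rat_l did not set that level (42.4% higher). With total antibody UMIs 39 passed (38.5% higher). The count was 12 at resolution 0.5 (75% higher), 17 at 1.5 (88.2%) and 13 with lineage from RNA and surface together (53.8%). Single cells held 77.6% and 45.7% of the IgG1_Rat_l UMIs in libraries 1 and 2; the cause of the moves was not tested. Of 12 lists past the threshold 6 remained with an estimated correlation, and fry, which does not compare lists with other genes, called 20.

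Without the replicate block the RNA count was 4929, of which 4923 were shared, and the antibody counts of immature-like subclusters 0 to 3 went from 45, 27, 18 and 22 to 25, 16, 5 and 9 (with other subclusters of at least 5% only as reference 48, 23, 11 and 34); 13 lists passed in place of 12, and no other count moved by over 1.5 times. The lineage comparison moved from 1157 to 2301 genes with late cDC1 alone. In cell composition, the mature-like share of cDC1 (9.99%) was 11.97% with doublets kept and 12.41% with the stricter cell filter, and 9.84% to 10.1% with each library alone, where fold changes are values with no test. Reversed were Mfge8 (-1.01 and -0.91), Gramd1b (-0.21 and -0.43) and Rpl8 (0.011 and 0.0015) at resolution 0.5 and with lineage from RNA and surface together, Mki67 (1.21) at resolution 1.5 and Ifit3 (-0.59) with the stricter filter. The settings that reversed Mfge8 and Gramd1b left the Ccr7-high cluster without a name, and both genes were above immature-like cells only in mature-like subcluster 2; for the others the cause was not tested. Of the other values of single genes, antibodies and lists under an alternative, 1406 kept their side of the threshold or, without a test, stayed within 1 log2 unit. Values that changed direction while past the threshold in neither setting were counted among these. A further 111 were no longer past the threshold, 10 newly passed and 2 moved. Depth left Abca1 undecided. Itgb8 fell below the filter on low counts, at 0.906 and 0.559 CPM in mature-like and 0.0151 and 0 in immature-like cDC1 (libraries 1 and 2).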

Other observations

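The test of single libraries was chosen only after its result was seen. A cluster without a name (459 and 514 cells per library) had Cd209a at 623.4 and 517.3 CPM and C1qa at 137.9 and 99.8 CPM, with surface CD172a at 13.5 and 11.5 UMIs per cell. Another of 141 and 167 cells had the granule genes Mpo (1167 and 963.9 CPM) and Elane (1826 and 2063 CPM), and a cluster of 32 and 36 cells had the antibody chain gene Jchain at 43356 and 37861 CPM.

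Interferon-stimulated genes were lower in late than in early mature-like cDC1 (adjusted p = 1.6e-05, 0.188 with an estimated correlation, which ended the call). A single library as the whole source was excluded, since the list median was below 0 in both, with -1.73 as the higher of the 2 values and -2.41 as the other. The early cells were themselves led by interferon-induced genes, so the subclustering may have picked them out. With subclustering resolution raised by 0.2, such cells formed a subcluster of their own (187 cells) apart from the lowest in mature markers, and Irf7 stood at log2 -3.19 and Cxcl10 at -3.30 between late and early. No biological explanation was tested.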
